A study of Schizosaccharomyces pombe with 3 samples.

How the data were processed

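Rec12 is the fission yeast (Schizosaccharomyces pombe) counterpart of Spo11, the protein that makes the DNA double-strand breaks of meiosis and stays attached to a short piece of DNA from each broken end. These short pieces, called oligos from here on, mark where breaks were made. The material was 3 libraries of oligos recovered with flag-tagged Rec12 from cells carrying pat1-114, a temperature-sensitive allele of the kinase gene that holds back meiosis. Per the labels, 1 library came from a haploid culture and was sequenced on the 454 platform, and 2 libraries came from separate adaptor ligations of material from a single diploid culture and were sequenced on the SOLiD platform. The latter are technical replicates, so each ploidy rests on 1 culture, and ploidy and platform differ together.

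Per the labels' protocols, meiosis was run at 30 °C and cells were collected at 4.5 hr, tagged Rec12 was immunoprecipitated from denatured extracts, and proteinase K freed the oligos. Both ends were G-tailed in turn and ligated to adaptors, and 16 cycles of PCR followed. The authors deposited whole-number counts of uniquely mapping oligos at each genome position, with a column per library, no normalization and no separation of strands, as the headers and values of the file show. A further table deposited by the authors holds expected counts (estimated counts that need not be whole) of oligos that map to several places, shared out over those places by a rule that is not given in the sources used here. The aligner, genome build, filters and the end of the oligo that a position stands for are also not given in the sources used here. G-tailing leaves the exact end of an oligo ambiguous where it borders a G or C, and how that was settled is not given either.

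Coordinates were read against the S. pombe reference assembly ASM294v3 and its annotation, after checking that they fit. Of the uniquely mapped positions, 0.0130% on chromosome I, 0.00719% on II and 0.0272% on III lay where neither adjoining 25-base word is unique in that assembly, against 0.540%, 0.578% and 1.22% after moving the positions by 500 bp. Base composition around the positions was symmetric about offset 0 in 25 of 25 segments of 500 kb. A position counted as mappable if a 25-base word starting or ending there was unique, which held for 12048576 of 12571820 bp (95.8%) of the 3 chromosomes, and densities are oligos per mappable bp, given as a multiple of the library mean. The tables also list positions on mitochondrial DNA and on a mating-type contig that is not part of the assembly used here, and those positions entered no density.

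Unique counts totalled 164978 in the haploid 454 library, 1529153 in diploid SOLiD replicate 1 and 2540337 in diploid SOLiD replicate 2, of which 163686, 1527716 and 2537174 lay on the 3 chromosomes. Multi-mapping oligos made up 16.0%, 25.2% and 19.2% of all oligos. They were used for repeats and for an alternative hotspot count. PCR copies could not be recognised without molecular identifiers, so binomial and Wilson intervals (95%) and the floor of 3 counts cover counting error only.

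The main values use the summed SOLiD libraries, and each library was also run alone. Hotspots were regions in which the oligo density, smoothed with a 500 bp Hann window, reached 5 times the mean. Regions closer than 200 bp were merged, and regions under 25 oligos were dropped. Density over intergenic sequence, annotated classes and chromosome regions was tested by shifting the oligo profile around each chromosome 1000 times, which keeps its clustering, with 95% bootstrap intervals over 100 kb blocks. Types of intergenic region were permuted 10000 times within 10 bins of length, and length was set against density by Spearman's rho with 10000 permutations. Gene lists were compared by their median density with 10000 random lists matched on length, motifs with 10000 draws of random intergenic positions, and hotspot spacing with 10000 random placements. These are permutation tests in the broad sense, in which shifted, permuted or randomly drawn versions of the data set the chance level. All tests are two-sided and adjusted within their family by the Benjamini-Hochberg method at 0.05. They set parts of the genome against each other within 1 culture, so they say nothing of how cultures vary. No test of haploid against diploid was possible.

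Classes were coding sequence, introns, 5' and 3' untranslated regions (UTRs) outside coding sequence, non-coding RNA genes outside protein-coding genes, tRNA genes, LTRs and Tf2 transposons, pseudogenes, and sequence outside every annotated gene. Centromeres were taken as the longest gap between protein-coding genes on each chromosome. An intergenic or upstream region needed 50 mappable bp. The 10 gene lists, the motifs and the rule for naming were fixed before the data were examined. The rule named the 20 hotspots with the largest share that also reached 5 times the mean in the 454 library, the 5 highest and 5 lowest ratios of 454 to SOLiD share, the 5 least dense intergenic regions over 2000 bp, and from each list the 2 members with the densest and the 1 with the least dense upstream region. These highest and lowest 454 to SOLiD ratios were taken over hotspots with at least 50 oligos in the 3 libraries together. Of the listed genes, 24 of 25 transport and 15 of 16 cell cycle symbols were found in the annotation, and every symbol of the other lists.

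The planned cross-correlation of the 5' ends of opposite strands could not be made from merged strands. An autocorrelation of the merged profile was computed in its place, at offsets up to 60 bp and relative to its mean at 41 to 60 bp. Alternatives covered the smoothing window, threshold, merging, minimum count, multi-mapping oligos, either SOLiD library or the 454 library alone, at most 10 oligos per position and library, gene boundaries, upstream definition, motif distance, window size and distance from chromosome ends. Leaving lncRNA genes out of the gene boundaries, and limiting positions to 10 oligos in the autocorrelation, were added after seeing the data.

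On simulated oligos, 200 of 200 planted hotspots of 10-fold density and 200 of 200 of 30-fold were found, 0 of 200 of 3-fold, and no false ones. A planted intergenic excess of 1 on the log2 scale was recovered as 1.00. Without a planted difference, 12 of 180 shift and permutation tests had p under 0.05, and 0 of 200 lists and 1 of 40 motifs passed after adjustment. With a planted 4-fold density, 81 of 100 lists of 12 measured genes had p under 0.05 in the list test before adjustment. Most lists had fewer measured genes for the intergenic region directly upstream, so this rate does not carry over to them. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.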

Results

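Oligos bound to Rec12 were mapped in 3 libraries from meiotic cells to find where on the chromosomes meiotic DNA breaks were made. The haploid 454 library placed 163686 unique oligos at 89896 positions of the 3 chromosomes. Diploid SOLiD replicate 1 placed 1527716 at 492582 positions, and diploid SOLiD replicate 2 placed 2537174 at 645202. Each group is 1 culture, and there was no control without Rec12 or without breaks, so values have no spread between cultures and no background to set them against.

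Breaks were concentrated in 553 hotspots, which covered 3.87% of the mappable genome and held 67.6% of the summed SOLiD oligos. The largest share of the summed oligos, 1.40%, lay over ade6, a purine synthesis gene on chromosome III (1316118 to 1318407), at 73.7 times the mean density in SOLiD and 39.2 times in the 454 library. Its first place came from SOLiD replicate 1 (1.58%). In replicate 2 its 1.29% was below the shares of hotspots 2 (1.33%) and 3. In the 454 library it had 0.745%, against 1.37% at hotspot 2. Whether the strains carried the reference sequence at ade6 was not examined, so these values need not describe the native gene. Hotspot 2 lay between peg1 and pdc201, a pyruvate decarboxylase gene, on chromosome I (3157694 to 3160334, 1.27%), and hotspot 3 between cyc3 and ste11, the transcription factor gene that starts sexual development, on chromosome II (3980085 to 3983566, 1.27%). The stretch from rpn502 to mae1, which encodes a malate transporter, was shorter but denser (chromosome I, 4910944 to 4912176, 0.878% of oligos, 88.7 times the mean). The median hotspot was 544 bp wide with 0.0472%.

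The other named hotspots on chromosome I, in order of share, were ymc1 to SPAC4G9.22, pcs2 to hsr1, eme1 to glt1 (glutamate synthase, 0.806%), ayr1 to pho842, gpa2 (a glucose-sensing G protein) to avl9, SPAC1834.13 to pex7, ptl2 to SPAC1786.04, pan3 to bsu1, and mug115 to SPAC56F8.15. Chromosome II had ubc1 to gsf1, gap1 (a Ras regulator) to sds23, alp4 to SPBC365.16, lsd90 to SPBC16E9.20, SPBC1685.17 to fhn1 and SPBC713.14C to erg1, and chromosome III had hel2 to nmt1, a thiamine synthesis gene (1837075 to 1839981, 0.892%). Of the 20 named hotspots, 18 peaked inside an annotated non-coding RNA gene, 1 inside coding sequence (ade6) and 1 outside every gene. Together they held 17.4% of the SOLiD oligos. Between the flanking coding genes, 11 were divergent, 8 tandem and 0 convergent.

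**Figure D1:**
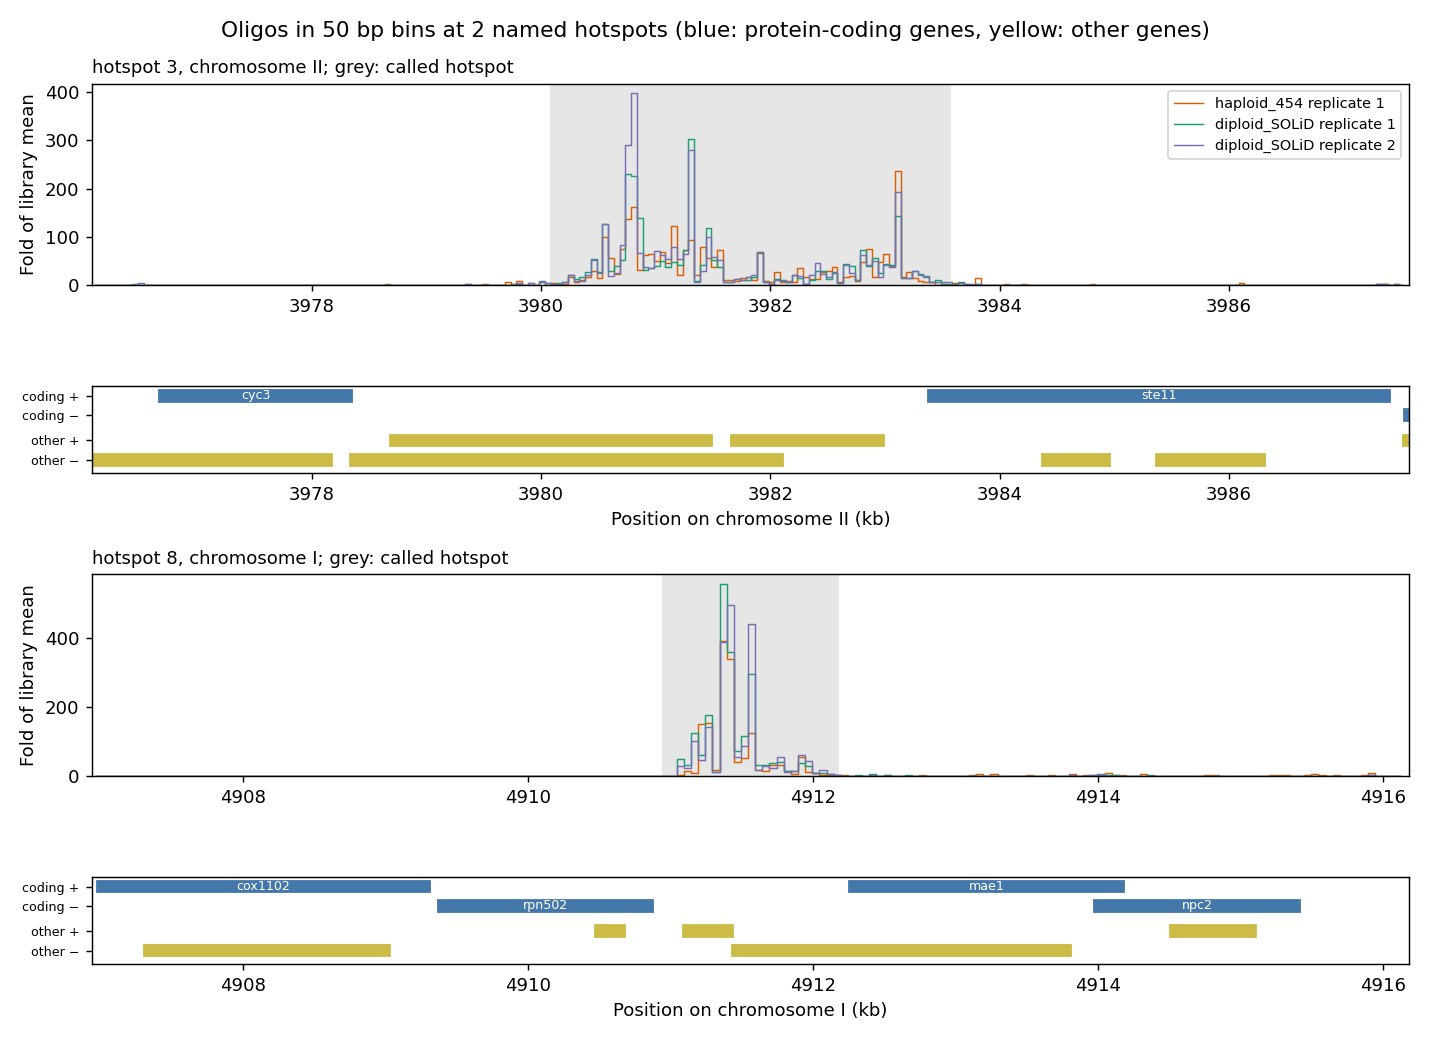
Oligo density in 50 bp bins (vertical axis, multiple of each library's mean) along chromosomes II and I (horizontal axis, kb) at hotspot 3, between cyc3 and ste11, and hotspot 8, between rpn502 and mae1, with 1 line per library, the called hotspot in grey and annotated genes as boxes. At both sites the density is low over most of the neighbouring coding genes in all 3 libraries.

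Over all 553 hotspots, 276 (49.9%) peaked in a non-coding RNA gene, 126 in sequence outside every gene, 54 in a 5' UTR, 54 in a 3' UTR and 35 in coding sequence. With lncRNA genes disregarded, 209 peaks lay between divergent genes, 181 between tandem genes, 12 between convergent genes and 151 inside a gene. The genome has 1328 divergent, 2328 tandem and 607 convergent regions, but these differ in length. Those with enough mappable sequence held 1163117, 1200267 and 169882 mappable bp in the same order. Numbers of regions therefore overstate the contrast between types. Hotspots numbered 44.3 per Mb on chromosome I, 44.8 on II and 51.8 on III. Called hotspots were spaced less evenly than random placement, with a coefficient of variation of 1.20. It was 0.253 above that of random placement (permutation test, p = 0.0001, the smallest 10000 placements can give). It was 0.157 above that of placement within intergenic regions of at least 500 bp (permutation test, p = 0.001). Merging at 1000 bp left 441 hotspots, and spacing was not tested with that merging. Clustering of separate hotspots is therefore not told apart from broad hotspots called in pieces. The longest stretch without a hotspot, 228 kb on chromosome III (1038133 to 1265979), holds the centromere and 65 protein-coding genes and had 0.234 times the mean density. The next, 167 kb on chromosome I (3579627 to 3746993), holds 72 protein-coding genes and no centromere, at 0.248 times the mean. The count depended on the smoothing, with 868 hotspots from a 200 bp window, and the 454 library alone gave 400. The minimum oligo count per region was the same for every library, so narrow regions are more easily dropped at the lower 454 depth. How much of the lower 454 count comes from this was not tested.

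The SOLiD libraries, ligated separately from the same culture, gave nearly the same map, and the haploid 454 library had a flatter profile. Of 552 hotspots called in SOLiD replicate 1, 523 overlapped 1 called in replicate 2, and shares per hotspot had Spearman's rho 0.992. In the 454 library, 371 of the 553 SOLiD hotspots reached 5 times its mean and 532 lay above it, with rho 0.920 for the shares. It had 51.8% of its oligos in these hotspots, against 66.6% and 68.1% in the SOLiD libraries, and 53.0% in the 400 hotspots called from it alone, which covered 3.18% of the mappable genome. The values for those 400 can be lowered by its depth, since the minimum oligo count per region was not scaled to the library. Because the 553 hotspots were selected on SOLiD density, ratios of 454 to SOLiD share over them can lean below 1, by an amount that was not measured. The median ratio of 454 to SOLiD share was 0.662, with 371 hotspots within 2-fold, 176 at or under 0.5 and 6 at or over 2.

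Among the named hotspots the ratio ran from 0.532 at ade6 (95% interval 0.502 to 0.563) to 1.14 at mug115 to SPAC56F8.15 (1.07 to 1.21), and 4 of 20 were above 1. Among all hotspots with at least 50 oligos, the highest ratio was at zrt1, a zinc transporter gene (3.04, 2.61 to 3.53). Next came mug153 (2.94), the stretch between rga7 and mat1-Mi, beside the mating-type locus (2.80), nep2 (2.53) and the stretch between msi2 and gnd1 (2.15). The lowest ratios were at 5 narrow hotspots in which the 454 library had 0 oligos, at top2 to SPBC1A4.04, SPBPB2B2.07C to SPBPB2B2.08, cyc2 to pro2, meu10 and spt3. Their upper limits ran from 0.188 to 0.363. They spanned 29 to 193 bp, and the 5 high ones 136 to 386 bp, all small beside the median. Ploidy, platform and culture differ together here, so none of these ratios is a test of ploidy.

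Across 12070 windows of 1 kb, which are not independent replicates, log2 densities correlated with Pearson's r 0.963 (Spearman's rho 0.850) between the SOLiD libraries and 0.675 (0.494) between the 454 library and the SOLiD sum. SOLiD replicate 1 thinned to the depth of the 454 library still had r 0.809 with replicate 2. Counts of the SOLiD pair differed by more than Poisson noise of independent oligos (chi-square per degree of freedom 2.94). With 10 kb windows the 454 value rose to 0.909, and with 200 bp windows it was 0.548.

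**Figure D2:**
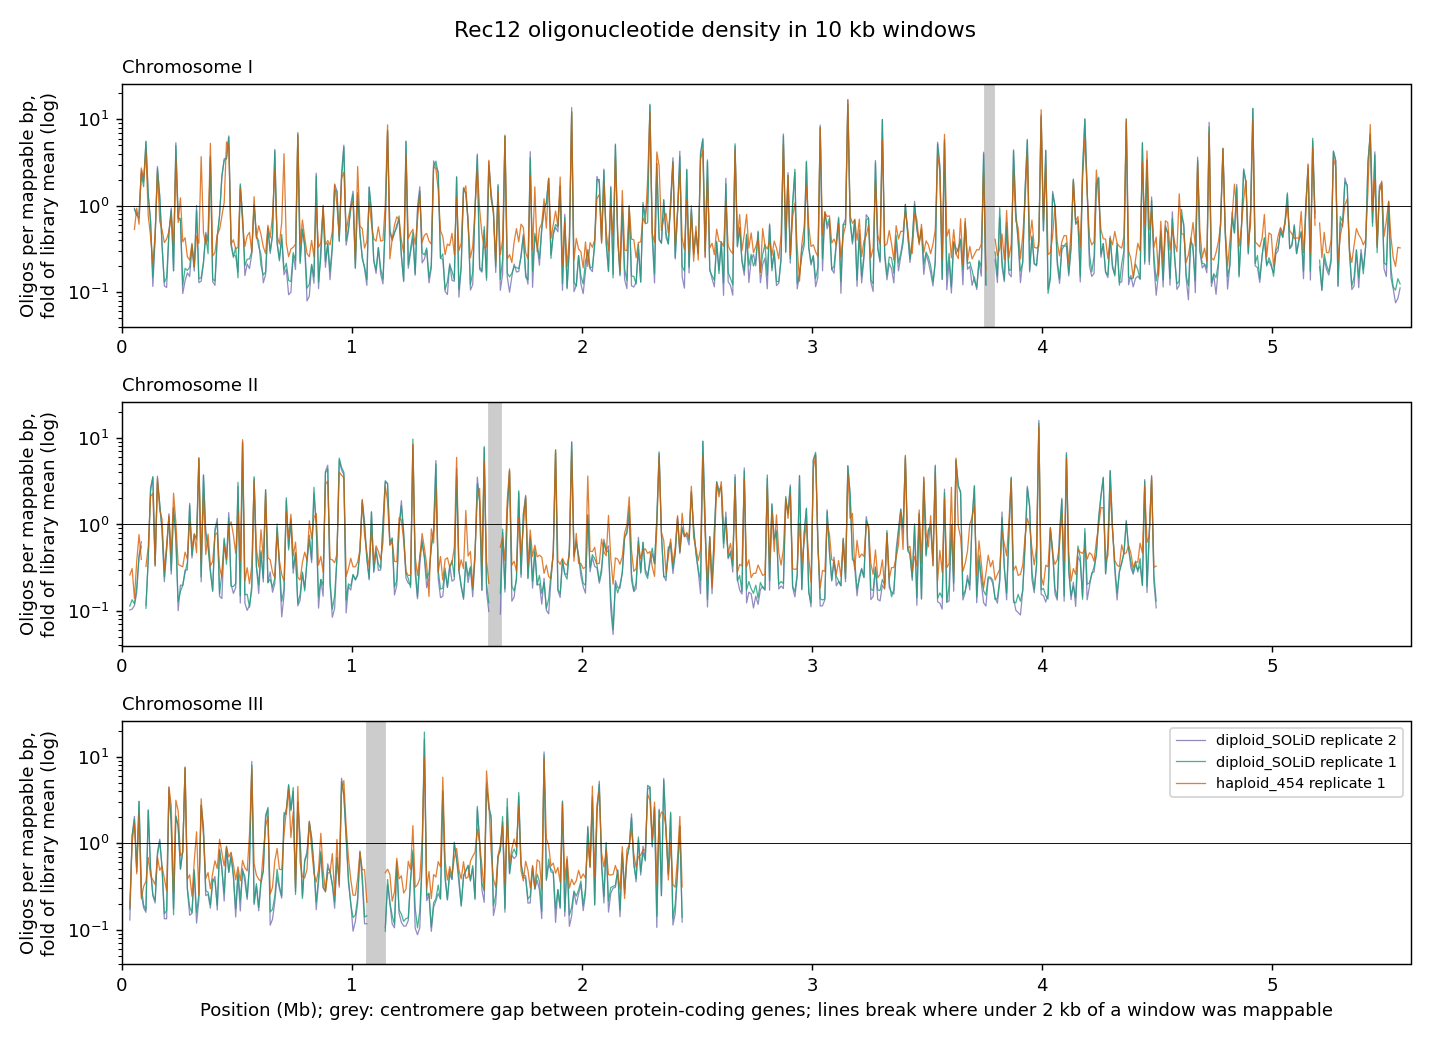
Oligo density in 10 kb windows (vertical axis, log scale, multiple of each library's mean) along the 3 chromosomes (horizontal axis, Mb), with 1 line per library and centromere gaps in grey. The libraries share their peaks, and the 454 line stays higher than the others in most low stretches.

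Sequence between genes was richer in breaks than genes, and most of that contrast lay with coding sequence. Coding sequence had 0.267 times the mean density (log2 -1.90, 95% interval -2.10 to -1.68), introns 0.479 times (log2 -1.06) and 3' UTRs 0.746 times (log2 -0.42). Non-coding RNA genes stood highest at 4.12 times the mean (log2 2.04, 1.91 to 2.17), followed by sequence outside every gene at 1.79 times and 5' UTRs (log2 0.58). tRNA genes had 0.0933 times the mean. These 7 classes passed (permutation test, adjusted p = 0.0013 each, near the smallest that 1000 shifts allow), while LTRs and transposons (log2 -0.64, adjusted p = 0.38) and pseudogenes (log2 -1.36, adjusted p = 0.39) did not. In the 454 library coding sequence was less depleted (log2 -1.11), as were tRNA genes (log2 -1.84), and LTRs and transposons passed (log2 -1.30, permutation test, adjusted p = 0.013).

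**Figure D3:**
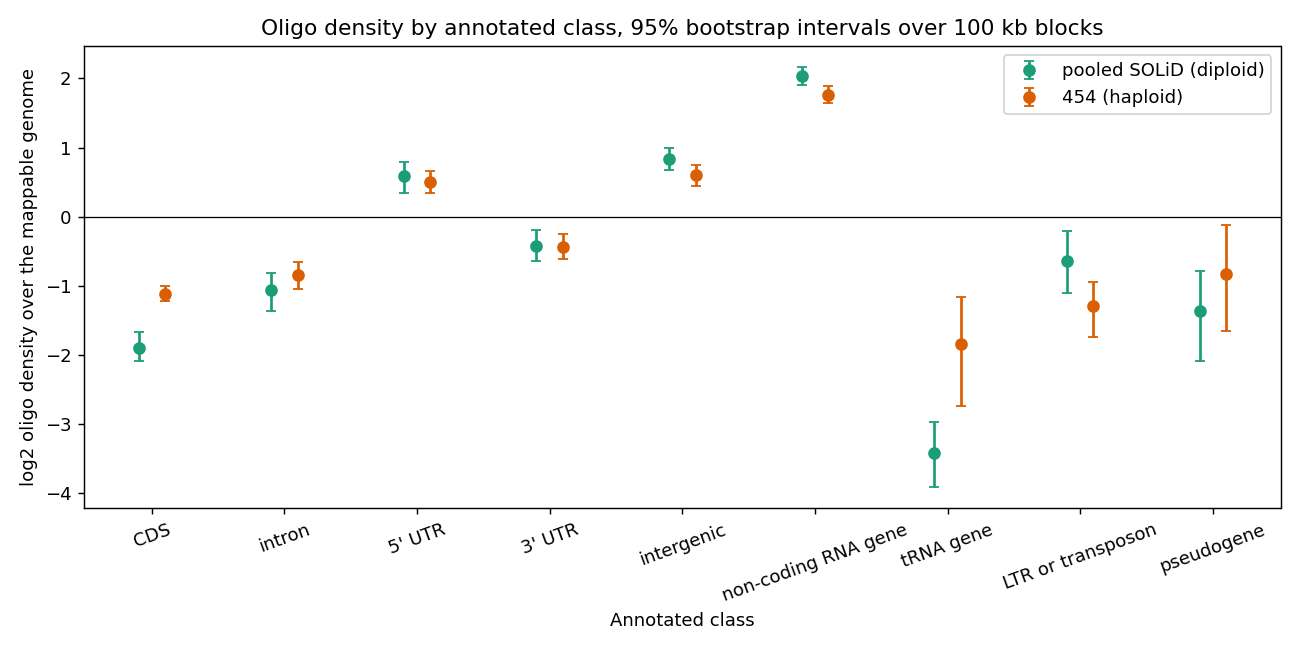
Oligo density over each annotated class as log2 of its ratio to the mappable genome (vertical axis), with 95% bootstrap intervals over 100 kb blocks, for the summed SOLiD libraries and the haploid 454 library. Non-coding RNA genes are highest and tRNA genes lowest in SOLiD, at 2.04 and -3.42.

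Taken over all annotated genes, intergenic density was 1.95 times genic density (log2 0.97, 0.75 to 1.16, permutation test, p = 0.001) in SOLiD and 1.60 times in the 454 library (log2 0.68). The size of this contrast depended on where genes were taken to end. It was 2.81 on the log2 scale with lncRNA genes left out of the gene boundaries and 2.98 with coding sequence alone.

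Regions between divergent genes, where both promoters lie, were denser than regions between convergent genes, where both genes end. Divergent regions had 2.06 times the mean density, tandem regions 1.93 times and convergent regions 1.28 times. Divergent exceeded convergent by 0.69 on the log2 scale, against 0.02 after permuting the types within length bins (971 divergent regions, permutation test, adjusted p = 0.0086). The difference of divergent from tandem, 0.10, did not pass (permutation test, adjusted p = 0.56). With lncRNA genes left out the divergent to convergent contrast was 1.39 (permutation test, adjusted p = 0.048), and with coding sequence alone it was 1.99. Density rose with length weakly when any gene ends a region (rho 0.12 over 3668 regions, p = 0.0001) and more so without lncRNA genes (rho 0.39) or between coding sequences (rho 0.51). With any gene as an end, the longest classes had lower densities, but they hold few regions. The 14 regions of 2000 to 3000 bp had 0.937 times the mean and the 10 over 3000 bp 0.145 times, with 0 at 5 times the mean. The 1729 regions under 200 bp had 1.57 times. The 10 longest regions had only 14521 mappable bp in all, so much of their sequence was not measured. These classes therefore do not show a reversal of the trend with length.

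Without lncRNA genes, the 146 regions of 2000 to 3000 bp had 6.06 times the mean density and 30.8% of them reached 5 times the mean, against 0.879 times and 1.54% for the 912 regions under 200 bp. The 88 regions over 3000 bp were lower again, at 5.12 times and 27.3%, and their median was 0.791 times the mean against 1.68 at 2000 to 3000 bp. With lncRNA genes again among the ends, 16 regions over 2000 bp had more than 50% of their bases mappable. The 5 least dense of these all lay near the right end of chromosome I, between prl61 and SPAC186.08C (5546649 to 5548883, 0.0676 times the mean), SPNCRNA.96 and prl104, SPAC186.03 and SPAC186.04C, SPNCRNA.4501 and SPAC750.02C, and SPAC186.08C and prl107, with values up to 0.0996.

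Density was low in the outermost chromosome ends and in centromere cores, but none of the chromosome regions tested passed the threshold. The first 50 kb had 0.346 times the mean density (0.555 in the 454 library) and the next 50 kb 1.03 times. Centromere cores had 0.121 times the mean and the 50 kb on either side 0.859 times. Within 100 kb of ends the log2 ratio to the rest was -0.28 (95% interval -1.13 to 0.24, permutation test, adjusted p = 0.57), within 50 kb it was -1.54 (adjusted p = 0.47), and around centromeres -0.33 (-1.89 to 0.48, adjusted p = 0.57). Chromosomes I, II and III differed from the rest by 0.03, -0.06 and 0.04, none past the threshold.

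Repeats, read with multi-mapping oligos included, were mostly poor in breaks. Tf2 transposons had 0.0259 times the mean in the 454 library, 0.0143 in SOLiD replicate 1 and 0.0125 in replicate 2, in the same order centromeres had 0.103, 0.0472 and 0.0416, LTRs 0.319, 0.573 and 0.532, and tRNA genes 0.492, 0.212 and 0.146. The annotated ribosomal DNA repeats had 1.55 times the mean in the 454 library and 0.508 and 0.555 in SOLiD. The assembly holds only part of the ribosomal DNA, and the rule by which the authors shared out multi-mapping oligos is unknown, so these levels carry both limits.

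Genes of glycolysis and of nutrient transport stood out among the 10 lists. The bodies of the 12 glycolysis genes had a median 0.758 times the mean against 0.163 for length-matched lists (log2 2.22, permutation test, adjusted p = 0.002), led by tdh1 at 4.88 times, fba1 at 4.48 and adh1 at 4.23. Bodies of the 24 transport genes had a median of 0.518 against 0.151 (log2 1.78, permutation test, adjusted p = 0.002). Bodies of the stress response (log2 1.09), histone (1.24) and chromosome structure (-0.38) lists did not pass after adjustment (permutation test, adjusted p = 0.096 each), although chromosome structure did with SOLiD replicate 2 alone (-0.46, adjusted p = 0.04) and stress response in the 454 library (0.88, adjusted p = 0.029). Values for the other lists, none of which passed, were 0.17 (meiotic recombination), -0.26 (meiotic and mating regulators), -0.0038 (sporulation), -0.12 (ribosomal proteins) and -0.08 (cell cycle).

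For the intergenic region directly upstream, no list passed, and few members of most lists had a region that could be measured. Glycolysis had log2 3.29 over 4 measured genes (permutation test, adjusted p = 0.096), transport 1.81 over 10 and ribosomal proteins 0.65 over 62, with the same adjusted p. In the 454 library alone the regions upstream of glycolysis (3.79, permutation test, adjusted p = 0.03) and transport genes (2.46, adjusted p = 0.016) passed. Values of the others were 2.13 (stress response), 0.85 (meiotic recombination), 0.08 (meiotic and mating regulators), 0.11 (histones), -1.54 (sporulation), -0.38 (cell cycle) and -0.21 (chromosome structure). With the 1000 bp before the coding start in place of that region, 3 lists passed, namely glycolysis (log2 4.20, permutation test, adjusted p = 0.001), transport (3.30, adjusted p = 0.001) and stress response (2.51, adjusted p = 0.002). With lncRNA genes left out of the boundaries histones (3.21) and ribosomal proteins (0.89) passed instead (permutation test, adjusted p = 0.001 each). In that setting glycolysis fell to 1.32 (permutation test, adjusted p = 0.24), transport to 1.34 (adjusted p = 0.072) and stress response to 1.44 (adjusted p = 0.1). Divergent neighbours within a list, such as rpl701 and rps1402, share 1 upstream region, which enters the median for each gene. Random lists were drawn gene by gene, so the list tests do not allow for shared regions.

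Single genes spanned a wide range. In the 1000 bp before the coding start mae1 had 86.8 times the mean, pho84 (a phosphate transporter) 16.6 and the least dense transport gene, ght8, 0.0948. Among glycolysis genes gpm1 had 19.4 and hxk2 19.1, and hxk1 had 0.803. In the stress list the small heat shock genes hsp16 and hsp9 had 19.1 and 8.47 and the chaperone gene hsp104 0.273. Ribosomal genes ran from rpp201 (21.9), followed by rps1102, to rps1902 (0.0771), and mei3, the inducer of meiosis, had 8.81, map2 1.54 and pat1 0.0711. Of the recombination genes mcp7 had 5.07, rec12 itself 4.23 and rec15 0.122. The sporulation genes spn7 (4.31), spn5 (2.19) and mde10 (0.107), the histone genes hht3 (3.29), hhf3 (1.97) and pht1 (0.346), the cell cycle genes wee1 (1.74), puc1 (1.60) and mik1 (0.0889) and the chromosome genes clr4 (0.989), swi6 (0.374) and psm3 (0.0711) gave lower ceilings. The lowest values rest on few oligos, and those of ght8 (0.150 in SOLiD replicate 1 and 0.0617 in replicate 2) and pat1 (0.110 and 0.0475) depended on the library. In the 454 library rpp201 had 4.56, below rps1102 at 10.1. There rec12 had 1.29 and hhf3 0.221 (3 oligos), while mcp7 (8.02) and map2 (2.94) were higher than in SOLiD. Over all 5069 measured genes the median was 0.296 and 305 reached 5 times the mean. Some of these values depended on the upstream definition. In the intergenic region directly upstream, SOLiD density was only 1.68 times the mean for rpp201 and 0.605 times for mcp7.

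In the region bounded by any gene, ste11 was highest at 45.8 times the mean (382 bp), although the 1000 bp before its coding start, which lie in its long 5' UTR, had 0.190. There hsp16 had 22.2, inv1 (invertase) 18.7, hxk2 14.7, eno101 6.79, mei2 3.93, isp5 3.45, rps2402 3.41, rpl2301 3.36, wee1 2.85, ctt1 2.56, meu13 2.41, spn5 2.15, rec24 0.947, clr4 0.757, swi6 0.638, hht2 0.289, cig2 0.286, hhf1 0.269 and spn6 0.118. The least dense members were pfk1 (2.15), gpx1 (1.21), rec10 (0.250), rum1 (0.225), pht1 (0.214), ght8 (0.124), top2 (0.121), mmi1 (0.0831), mde10 (0.0527) and rpl1701 (0.0430). Several of these short regions rest on few oligos, 1 in rpl1701 and 5 in mde10. In SOLiD replicates 1 and 2 alone rpl1701 had 0.114 and 0, mde10 0.0842 and 0.0338, pht1 0.355 and 0.128, and top2 0.231 and 0.0555.

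Averaged over protein-coding genes, break density was highest 500 bp before the coding start, at 1.66 and 1.70 times the mean in the SOLiD replicates, and was lowest 650 bp inside it, at 0.351 and 0.323. The 454 library was highest at 1.47 times, 950 bp before the start, and fell to 0.461 at 700 bp inside. The upstream rise was broad. SOLiD replicate 1 also had 1.64 at 950 bp and 1.65 at 300 bp before the start, and the 454 library 1.40 at 500 bp. The places of the maxima are therefore not well defined and do not show a shift between libraries.

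**Figure D4:**
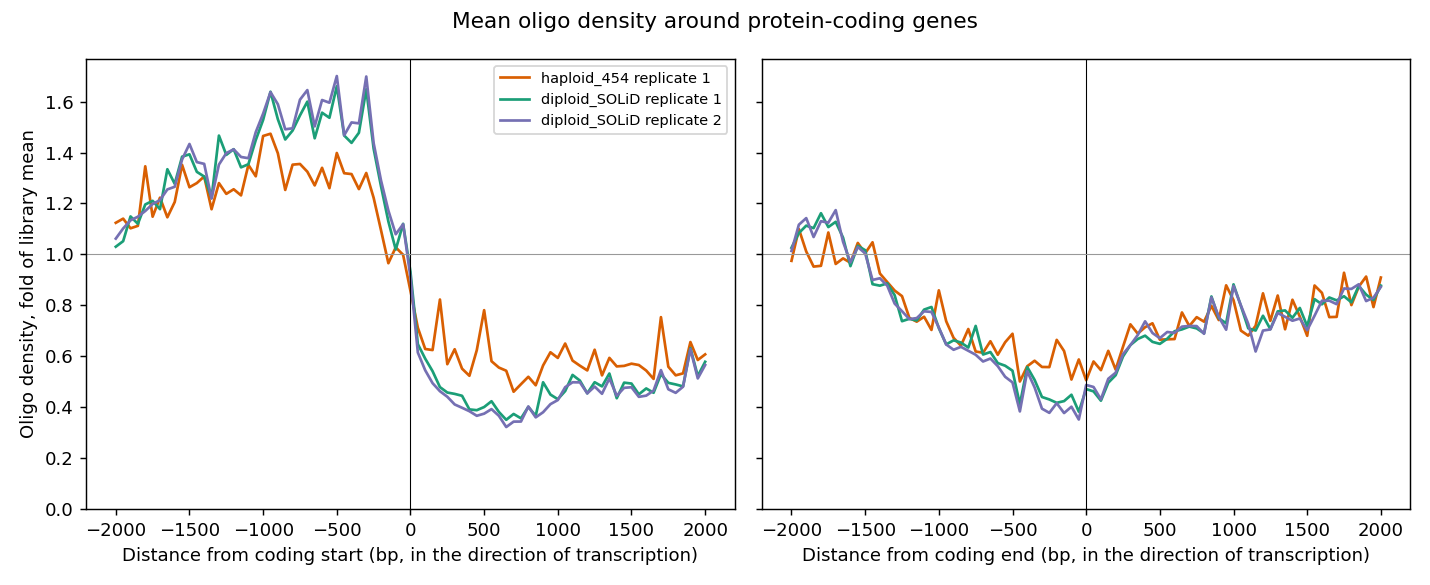
Mean oligo density (vertical axis, multiple of each library's mean) by distance in bp (horizontal axis) from the start and from the end of the coding sequence of protein-coding genes, with 1 line per library. Density is highest upstream of the start and lowest within genes, and the 454 line is flatter.

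Breaks were denser around several DNA motifs. Within 250 bp of 44 intergenic copies of the M26 heptamer (ATGACGT), a site bound by Atf1 and Pcr1, density was 6.40 times the mean against 1.78 around random intergenic positions (log2 1.85, permutation test, adjusted p = 0.0004). The CCAAT box (log2 0.94 over 85 copies, permutation test, adjusted p = 0.011) and runs of at least 10 A or T (0.43 over 531, adjusted p = 0.011) passed too. The 8 copies of the longer CRE site (TGACGTCA), which contains most of the heptamer, had log2 1.42 (permutation test, adjusted p = 0.065) and did not, except with at most 10 oligos per position (1.38, permutation test, adjusted p = 0.03). The oligo-C box and 2 other listed motifs had under 3 intergenic copies and were not tested. Without lncRNA genes the M26 value was 1.03 over 105 copies (permutation test, adjusted p = 0.004).

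Bases at the mapped position and 1 base to either side differed between platforms, while those 4 bases to either side were alike in kind. At the position itself G or C made up 54.2% of oligos in the 454 library, 21.1% in SOLiD replicate 1 and 20.2% in replicate 2, against 36.1% in the genome. At 4 bases before it A rose to 38.9%, 43.2% and 44.6%, and at 4 bases after it T stood at 38.5%, 43.0% and 44.5%, against 31.9% and 32.0% in the genome. Positions often had a neighbour at 1 bp, where the autocorrelation was 6.22, 5.72 and 5.43 times its level at 41 to 60 bp. With at most 10 oligos per position these were 3.67, 2.36 and 2.15.

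**Figure D5:**
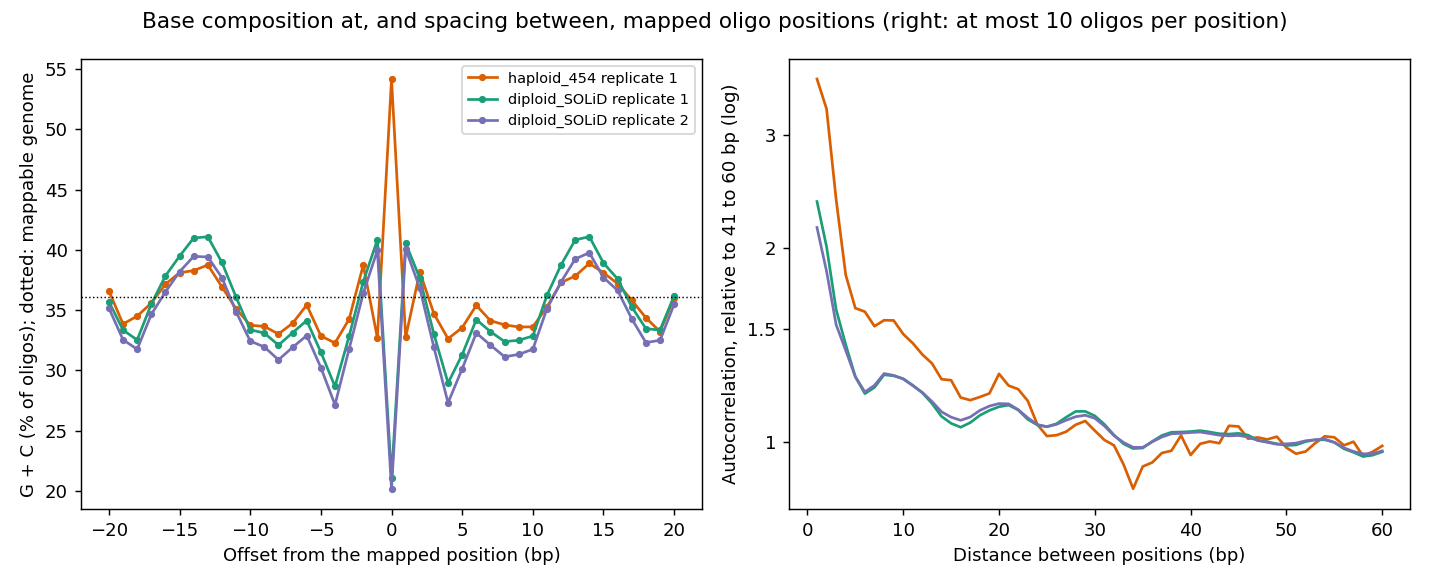
Left, share of G or C (vertical axis, %) by offset from the mapped position (horizontal axis, bp), 1 line per library, with the genome dotted. Right, autocorrelation of positions relative to 41 to 60 bp by distance in bp. The 454 line is at 54.2% at offset 0 and the SOLiD lines are at 21.1% and 20.2%.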

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

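Oligos also lay on DNA outside the main measurement, above the limit that 3 counts allow. Mitochondrial DNA took 0.709% of unique oligos in the haploid 454 library (Wilson interval 0.669% to 0.750%, limit 0.00182%), 0.0381% in diploid SOLiD replicate 1 and 0.0738% in replicate 2. The mating-type contig took 0.0746% (123 oligos), 0.0558% (854) and 0.0507% (1287) in the same order.

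For 6 gene list values the 454 library and both SOLiD libraries had opposite signs, and these differences between groups were not tested. In the order 454, SOLiD replicate 1 and SOLiD replicate 2, log2 values against matched lists were 0.54, -1.72 and -1.51 upstream of sporulation genes and 0.21, -0.60 and -0.20 upstream of cell cycle genes. Over gene bodies they were -0.42, 0.022 and 0.18 for meiotic recombination, 0.35, -0.26 and -0.092 for meiotic and mating regulators, 0.041, -0.029 and -0.046 for sporulation, and 0.067, -0.056 and -0.24 for ribosomal proteins. None of these passed the threshold in the 454 library or in the SOLiD sum. Upstream, the sporulation and cell cycle values rest on 3 measured genes each. The 454 library had 4, 2 and 0 oligos upstream of spn5, spn6 and mde10. It had 6, 0 and 3 upstream of wee1, cig2 and rum1, so its signs for these lists rest on few oligos.

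The share of G or C at the mapped position went opposite ways on the 2 platforms, at 18.1 percentage points over the genome in the 454 library and at -15.0 and -15.9 in the SOLiD replicates, a difference that was not tested across cultures. The explanation tested, with a test chosen after the pattern had been seen, was that the platforms place the end of an oligo 1 base apart. The product of 454 and SOLiD counts at an offset of 1 base was 0.990 times that at offset 0 (95% interval 0.983 to 0.997), against 0.669 between the SOLiD libraries, and a complete displacement would give 1.17. The ratio stayed under the bound of 1 written down before it was seen, and under 1.17, which argues against a complete displacement. It lies above that of the SOLiD pair, so a displacement of part of the oligos stays open, as do an end preference of each library's adaptors or platform, and ploidy, which was not tested. The 454 library had 27.2% C and 27.0% G at the position itself. In SOLiD the excess of C lay 1 base before the position and that of G 1 base after it. Such base shares go with a displacement of 1 base, and the test did not use them.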

How the results depend on the processing

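No paired analysis was possible because the haploid group is 1 library and the SOLiD libraries are technical replicates of a single culture. Of the positions, 67.9% held 1 oligo in the 454 library and 56.9% in SOLiD replicate 2, with replicate 1 between them. The planned division of each multi-mapping oligo by its number of places was not run, since the file already shares oligos out. The settings that leave lncRNA genes out, or limit positions to 10 oligos in the autocorrelation, were chosen after seeing the data. The cause of each change was not tested.

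The intergenic, feature class and spacing results kept direction and side of the threshold under every setting run, apart from LTRs and transposons, which passed in the 454 library (log2 -1.30). Spacing was not run with wider merging of hotspots. Of 184 alternative values of single members, 158 kept both, 11 crossed into passing and 15 changed sign, none of the last past a threshold in either setting. The hotspot count stayed within 1.5 times except for 868 with a 200 bp window. Window correlations were 0.894, 0.995 and 0.958 between SOLiD libraries with 200 bp windows, 10 kb windows and at most 10 oligos per position, and 0.548 and 0.909 for 454 against SOLiD with 200 bp and 10 kb windows.

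List tests that passed, upstream and body counted apart, numbered 5 in the 454 library alone (from 3 lists), and upstream 3 with a fixed 1000 bp and 2 without lncRNA genes. Changes of sign upstream were meiotic recombination at -0.19 without lncRNA genes and -0.55 with 1000 bp, mating regulators at -0.22 without lncRNA genes and -0.23 without SOLiD replicate 1 (0.0063, sign kept, without replicate 2), sporulation at 0.54 in the 454 library and 0.37 with 1000 bp, cell cycle at 0.21 in the 454 library, and chromosome structure at 0.10 without SOLiD replicate 2 (-0.16, sign kept, without replicate 1). Over bodies they were meiotic recombination at -0.42 in the 454 library and -0.069 with at most 10 oligos, mating regulators at 0.35, sporulation at 0.041 and ribosomal proteins at 0.067 in the 454 library, and cell cycle at 0.072 without SOLiD replicate 2 (-0.16, sign kept, without replicate 1). Chromosome I had -0.0053 with at most 10 oligos.

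In the order 454, SOLiD replicate 1 and 2, the autocorrelation at 1 bp was 3.67, 2.36 and 2.15 with at most 10 oligos and 2.33, 1.64 and 1.57 with each position counted once, and the G or C share at the position was then 51.8%, 24.9% and 24.8%.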

Other observations

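The gene for Rec12 held a hotspot of its own. The body of rec12 had 24.7 times the mean density in SOLiD, the highest of any listed gene, and the hotspot there (chromosome I, 1772656 to 1774401) took 0.303% of SOLiD oligos, with a 454 to SOLiD ratio of 0.416 (95% interval 0.360 to 0.477). Its partner gene rec7 had 8.17 times the mean over its body, with a hotspot peaking in its 3' UTR (chromosome III, 1546191 to 1548123) and a ratio of 0.527 (0.446 to 0.619). Both stood apart from a median of 0.181 over the bodies of the recombination list, and no explanation was tested for either. Rec12 was flag-tagged in these cells and the reference assembly holds no tag, so the rec12 values may not describe an untagged gene. The rec12 and rec7 genes were chosen after their values were seen, as were the hotspots in coding sequence that follow.

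Of the 35 hotspots that peaked in coding sequence, ade6 was the hottest and mug114, beside hxk2 on chromosome I (2662879 to 2665722), the next, with 0.394% of oligos at 16.7 times the mean. The hotspot in yme1 on chromosome III (2286798 to 2287713) was denser, at 29.2 times the mean in SOLiD and 30.6 times in the 454 library. The hotspot in SPAC5H10.10 on chromosome I (162447 to 163174) reached 9.39 times the mean in SOLiD and 1.31 in the 454 library, a ratio of 0.140 (0.0744 to 0.240).

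None of the tests in the following paragraphs was planned, and each was set down after its pattern had been noticed and before its own value was seen.

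Break positions tended to recur at steps of about 10 bases. With at most 10 oligos per position, the autocorrelation peaked at 8, 21 and 29 bp in SOLiD replicate 1, at 8, 20 and 29 bp in replicate 2 and at 20 and 29 bp in the 454 library. Troughs lay at 16 and 25 bp in both SOLiD libraries and at 17 and 25 bp in the 454 library. In SOLiD, drawing positions within hotspots by the base preferences in the 20 bases on either side gave a wave -0.107 times as strong as that of the oligos, so those preferences taken base by base do not account for the wave there, and no such draw was made for the 454 library. Between the separately ligated SOLiD libraries the wave was 0.966 times that within each. These waves were measured in hotspots with each position counted once, so copies at the same position had been removed beforehand. The ratio shows a wave shared by the SOLiD libraries, and it does not test such copies as a cause. No biological explanation was tested, and the distances used to measure the wave were picked from the same profile.

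The 454 library had more oligos over coding sequence than SOLiD, with log2 -1.11 against -1.90 relative to each mean. Counting noise is excluded as the whole cause, since 0 of 100 draws of SOLiD oligos at the 454 depth reached that density over coding sequence (highest -1.88). A candidate explanation is a layer of evenly spread DNA not released by Rec12 in the 454 library. Over the 2532 coding genes least dense in SOLiD, the A and T excess at 4 bases from the position was -0.146 times that in hotspots (-0.289 to 0.001), which goes with this explanation. SOLiD oligos over those genes kept part of the excess (95% interval 0.185 to 0.419), more than the 454 oligos did. They too fell under the bound of 0.5 set for the test, so such DNA is not ruled out in SOLiD, and ploidy and platform stay open.

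The hypothesis was tested that non-coding RNA genes are dense in breaks (log2 2.04 over the mean) only because they lie in long, dense intergenic regions. The test took 1413 intergenic regions with at least 100 mappable bp both inside and outside lncRNA genes, and 0.5 was added to each count. Within them the density inside lncRNA genes exceeded that outside by a median log2 of 0.12 (0.03 to 0.19), and 53.6% of regions were denser inside. A value above 0 goes against lying in dense regions as the whole cause over these regions. They were not chosen for length or density, so the median does not describe the long, dense ones alone. Position within a region was not controlled. In SOLiD replicate 1 density was 1.66 times the mean 500 bp before coding starts and 1.02 times 100 bp before. Position within regions therefore stays open as a cause of the median. Summed over regions, as the 2.04 is, the value was 1.03. Lying in long, dense regions may account for part of the difference, and how large a part stays open.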
